A study of Mus musculus with 8 samples.

How the data were processed

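RNA from mouse rib cartilage chondrocytes was profiled in 8 libraries, which fall into 4 groups of 2 by their labels. Per the labels' protocols, cartilage of 10-day-old CD1 mice was digested with collagenase, the cells were filtered and plated, and RNA was extracted with TRIzol. Per the series design text, sequencing used DNBSEQ. The submitters' processing notes name HISAT2 2.0.4 and the mm9 build. The read counter and the gene annotation are not given in the sources used here.

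The authors' deposited table lists 18501 genes. Per the file headers it gives a read count, here an estimated count, and an FPKM value per gene and library. The estimated counts were deposited by the authors with no normalization. The estimated counts were not whole for 2282 to 2518 genes per library and were rounded to whole numbers before any count test. Estimated counts of this kind can divide reads between near-identical genes, which affects the genes named below as copies. The deposited FPKM values were used for alternatives only, after addition of 1 or 0.1 and a log2 transformation. The authors' deposited table of comparisons gives log2 ratios and q-values for 2655 genes in 4 group comparisons; the tool behind those q-values is not given in the sources used here. A further table with 3 of the libraries held the same values for its 17730 genes and was not used. Symbols of 24 genes that a spreadsheet had turned into dates were restored from their Entrez IDs. Of the Entrez IDs, 18381 were found in the RefSeq gene table of GRCm38.p6, which served for names and gene order, and 3′ UTR sequences came from GENCODE M21 on GRCm38. Because the submitters name another build, no coordinates are given.

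Total counts ran from 26536868 to 28678641 per library. Counts of any 2 libraries differed by more than sampling noise, so no library was counted as a duplicate. The labels do not say whether the 2 libraries of a group came from separate animals or cultures. Y-linked Ddx3y was counted 2 and 2511 times in CG wild types, 3669 and 10 in CT wild types and 3512 and 30 in CT mutants. The 2 libraries of each of these groups therefore came from different animals. For CG mutants, at 2231 and 2360, this stays open. P-values measure the spread between these libraries, which may be in part technical. Labels share replicate numbers between groups but do not say what a number marks.

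Differential expression was tested with edgeR 4.0.16 in R 4.3.3, using its quasi-likelihood F test. A single fit held 4 group means over all 8 libraries, with TMM factors, the default filter on low counts, 14359 genes tested and 4 residual degrees of freedom. Standard errors were taken as the absolute log2 fold change divided by the square root of F. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The contrasts were the mutant effect in each line, their mean, their difference, and the difference between the wild types of the lines. CPM are counts scaled by the TMM-adjusted library size, given as mean ± SD over 2 libraries.

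Gene lists were fixed before the data were examined and tested with camera in limma 3.58.1, with a preset inter-gene correlation of 0.01 and adjustment over the 29 lists with measured members. Camera with a correlation estimated from the data and fry, a self-contained test counted here in its directional form, were alternatives. The camera test between the wild types and the lists of p53 targets and of neutrophil genes were chosen after the data were seen. Seed match sets held genes whose longest annotated 3′ UTR, of at least 50 bases, carried a 7-base or 8-base match to the seed of an arm of miR-140. The difference of medians between genes with and without a site was also ranked among all 7-mers found in at least 50 genes, after regression of the log2 fold change on log2 UTR length and GC fraction.

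The genes named were chosen by a rule fixed before the data were examined. For each mutant effect it took the 8 largest rises and falls among genes past the threshold, with a mean log2-CPM of at least 1 and both mutant libraries on the same side of both wild-type libraries. Where a direction had fewer than 5, the 5 smallest unadjusted p-values were taken and are said not to pass. Wwp2, Col2a1, Acan, Sox9, Col10a1, Col1a1 and Mki67 were always named. Reported miR-140 targets were named by the smallest p-values in each mutant comparison, so those named differ between comparisons. For the difference between the lines and between the wild types, 5 genes in each direction were taken. Unnamed gene models were passed over. Members of a list given as examples have the smallest p-values of the list in the mutant comparisons, and between the wild types they were picked after the data were seen.

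In counts simulated from the real means and dispersions with 200 changed genes, the fit recovered 67.2% of genes changed 2-fold and 95.5% of those changed 4-fold in the CG comparison, over 14209 genes. It recovered 77.6% and 97% of them in the CT comparison, over 14221 genes. For a 1.5-fold change the shares were 17.9% and 22.4%. Unchanged genes called numbered 7 in the CG and 9 in the CT comparison. The changed genes had a mean log2-CPM of at least 1, and no simulated library deviated as CG mutant replicate 1 did. These shares may therefore be too high for the real libraries. Alternatives were RLE size factors, DESeq2 1.42.0, filters on low counts, limma on FPKM, a replicate block, leaving out each library, and fits within a line. A robust fit, a term for sex and a crossed block were added after the data were seen.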

Results

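The libraries compare chondrocytes of 2 mouse lines in which the gene of miR-140, a microRNA abundant in cartilage, had been altered. In the CG line the seed region of the 3p arm was mutated, and in the CT line a C>T base change was made. Both are described as ways of overexpressing the 5p arm. Each line has its own wild-type group, and each of the 4 groups has 2 libraries. Total counts were 28267472 and 26536868 in the CG wild types and 27363768 and 26875777 in the CG mutants. They were 27633372 and 27627450 in the CT wild types and 28678641 and 27297539 in the CT mutants. The first principal component, with 64.5% of the variance, separated the lines. The second, with 12.2%, set CG mutant replicate 1 apart, at 47 against -8.4 for the other CG mutant library.

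**Figure D1:**
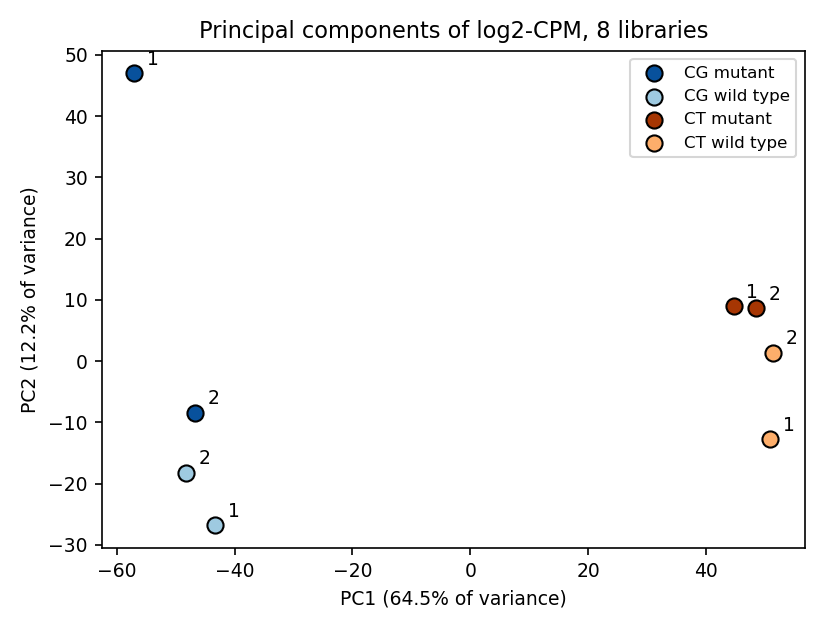
Principal components of log2-CPM, with the percentage of variance on each axis and 1 point per library, numbered by replicate and coloured by group. The lines separate along the first component, and CG mutant replicate 1 lies at 47 on the second.

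Neither the precursor of miR-140 nor its arms were analysed here. Wwp2, the ubiquitin ligase gene whose intron hosts the precursor, is given for its own mRNA and does not report the level of either arm. Wwp2 stood at 822 ± 312 CPM (SD, n = 2) in CG mutants and 493 ± 4.88 CPM in their wild types. The log2 fold change of 0.74 ± 0.28 (SE) did not pass the edgeR test, with an adjusted p of 0.384. The mutant libraries were at 1043 and 601.1 CPM, and the log2 fold change was 0.28 without replicate 1 and 1.08 without replicate 2. In the CT line Wwp2 was at 263 ± 81 CPM in mutants and 269 ± 36.7 CPM in wild types, a log2 fold change of -0.03 ± 0.28 with an edgeR p of 0.909 and an adjusted p of 0.998.

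The first comparison asks what the 3p seed mutation changed in the CG line. A single gene passed, Eif3j2, a near-identical copy of the translation initiation factor subunit gene Eif3j1. Its level was 1.17 ± 0.18 CPM in CG mutants and 93.8 ± 49.4 CPM in CG wild types, a log2 fold change of -6.32 ± 0.42 with an edgeR adjusted p of 0.00509. Reads of such copies can be divided between them in counting, so its level is uncertain. In a fit of the CG libraries alone Eif3j2 did not pass, and the 1 gene that did was Cwc22. The sum of Eif3j1 and Eif3j2 differed by a log2 value of 0.15 between CG mutants and wild types.

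Among genes that did not pass, the smallest p-values of higher genes in CG mutants belonged to Fbln2, Lmcd1, Palld, S1pr2 and Tshz2. Fbln2, which encodes the matrix protein fibulin 2, was at 32.5 ± 5.95 CPM in mutants and 12.4 ± 0.31 CPM in wild types, a log2 fold change of 1.39 ± 0.16 with an edgeR adjusted p of 0.08. Lmcd1 had a log2 fold change of 1.45 ± 0.17 and Palld, which encodes the actin-associated protein palladin, 1.24 ± 0.17. S1pr2, a sphingosine 1-phosphate receptor gene, was at 0.87 ± 0.12 and the transcription factor gene Tshz2 at 1 ± 0.13. The lower genes were Ccl5, Cmc2, Dio2 and Zfp970. The chemokine gene Ccl5 was at 372 ± 31 CPM in mutants and 866 ± 39.2 CPM in wild types, a log2 fold change of -1.22 ± 0.13. Cmc2 was at -1.06 ± 0.12, the thyroid hormone activating deiodinase gene Dio2 at -0.99 ± 0.12 and Zfp970 at -0.72 ± 0.09. Adjusted p-values of these 9 genes were from 0.08 to 0.0865. Y-linked Ddx3y was detected in both CG mutants but in only 1 of the CG wild types. With a term for sex, 3 genes had an edgeR adjusted p under 0.1 in this comparison, against 13 without it.

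Of the cartilage genes, Col2a1, the main collagen of cartilage, had a log2 fold change of 0.36 ± 0.27 in the CG line, and the proteoglycan gene Acan 0.54 ± 0.27. Sox9, the transcription factor of the chondrocyte lineage, was at 0.37 ± 0.22. The hypertrophic collagen gene Col10a1 was at -0.14 ± 0.18, Col1a1 at -0.62 ± 0.42 and the proliferation marker Mki67 at -0.21 ± 0.23. None of these 6 passed, with edgeR adjusted p-values from 0.491 to 0.801.

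Taken as groups, 7 of 29 gene lists moved in the CG line by camera with a preset correlation, 1 upward and 6 downward. With an estimated correlation none of the 29 passed, the smallest adjusted p being 0.75. The chondrocyte matrix and identity list rose, with a median log2 fold change of 0.39, 18 of 26 members above 0 and an adjusted p of 0.0122. Its members with the smallest p-values were Ucma at 1.44 ± 0.29, Cytl1 at 1.59 ± 0.45 and Sox6 at 0.81 ± 0.25, none of which passed over all genes. The inflammatory and NF-kB list fell, with a median of -0.43, 1 of 20 members above 0 and an adjusted p of 0.000106. It was led by the chemokine genes Cxcl1 at -1.44 ± 0.43 and Cxcl2 at -1.54 ± 0.60. Immediate early and dissociation stress genes fell with a median of -0.37, 1 of 17 members lying above 0 and an adjusted p of 0.000147. Macrophage and leukocyte markers fell with a median of -0.44 and an adjusted p of 0.00855, and tendon and ligament genes, led by Scx, with a median of -0.53 and an adjusted p of 0.0108. Cell cycle genes had a median of -0.19 and an adjusted p of 0.0122. No member of any of these lists passed over all genes, and adjusted over the list alone 1 chondrocyte gene and 1 cell cycle gene, Ccnd1, were higher.

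The list of 16 measured genes reported as targets of miR-140-5p passed downward in the CG line by camera with a preset correlation, with a median log2 fold change of -0.24 and an adjusted p of 0.0239. With an estimated correlation its adjusted p was 0.75. No member passed, and 3 were above 0. The smallest p-values among them were those of Nfe2l2 at -0.39 ± 0.13, Loxl3 at 0.50 ± 0.20, Tgfbr1 at -0.25 ± 0.11 and Mmp13 at -0.89 ± 0.39. Of the 3 reported miR-140-3p targets, Nrip1 was at -0.28 ± 0.12 and Ncoa1 at -0.12 ± 0.11, and the list had an adjusted p of 0.155.

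The other 22 lists had adjusted p-values from 0.113 to 0.988 in the CG line. Of these 7 calls, 6 were lost without CG mutant replicate 1. Without it the chondrocyte list had a median of -0.03 and an adjusted p of 0.918, the inflammatory list -0.21 and 0.207, the macrophage list 0.15 and 0.613, and the reported 5p targets -0.04 and 0.629. The cell cycle and tendon lists each had an adjusted p of 0.492. Immediate early genes still passed, with an adjusted p of 0.0219, but their median was -0.15, against -0.65 without CG mutant replicate 2. Without that replicate the medians of the other lists were also larger, at -1.22 for the inflammatory, -1.67 for the macrophage, -1.01 for the tendon, -0.42 for the cell cycle and 0.66 for the chondrocyte list. The reported 5p targets had a median of -0.14 without CG wild type replicate 1. The Y-linked gene Ddx3y was counted 2 times in CG wild type replicate 1 and 2231 to 2511 times in the other CG libraries. Without CG mutant replicate 2 edgeR called 522 genes. In this line 1633 genes had an unadjusted p under 0.05, DESeq2 called 205 genes, 111 higher and 94 lower, and the authors' deposited table lists 108 with a q-value under 0.05. That table holds few of the genes lower in CT wild types, 29 of 2407, so its counts cover part of the genes and cannot be set against the others.

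**Figure D2:**
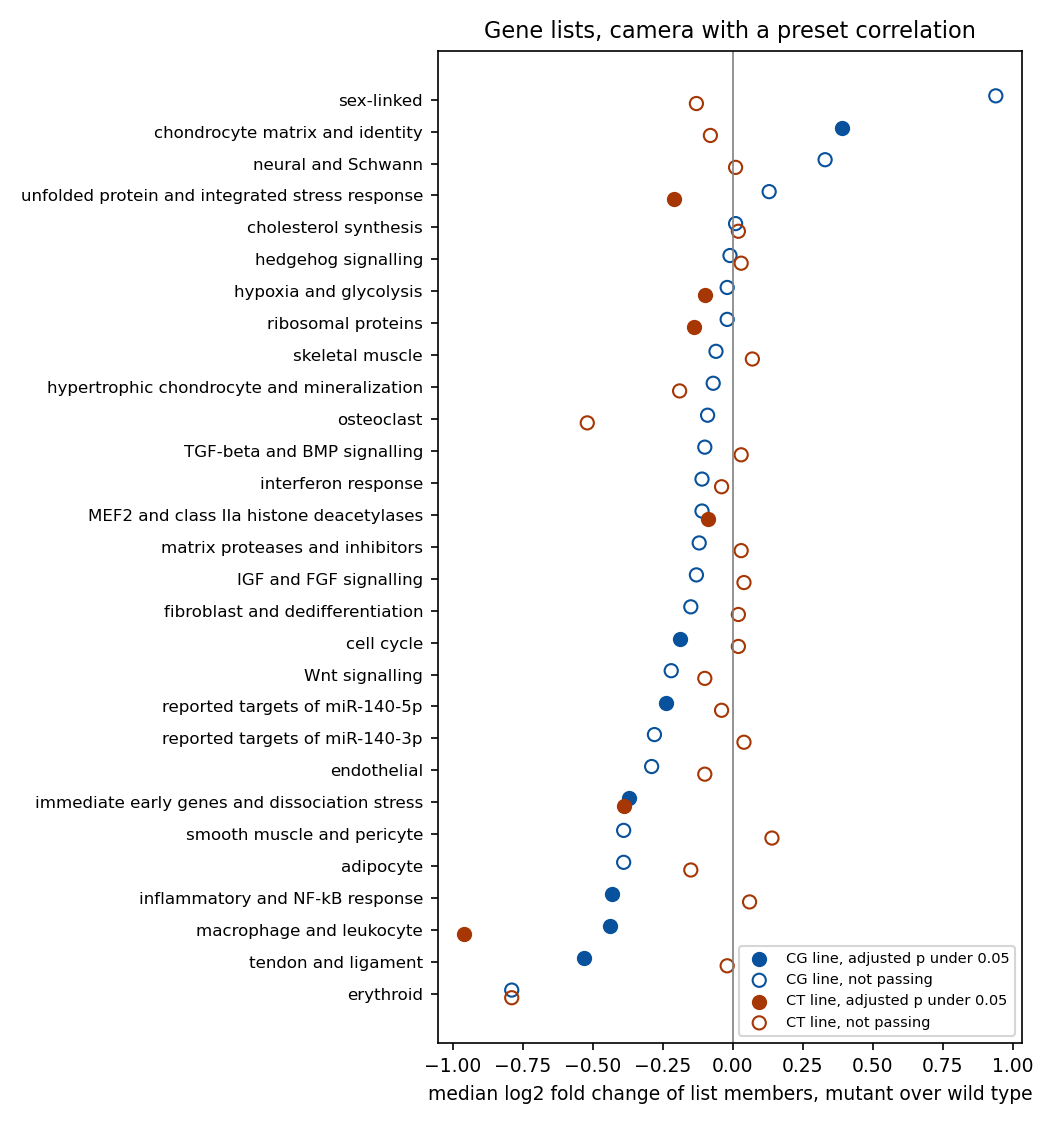
Median log2 fold change of the members of each gene list, mutant over wild type, with the CG line in blue and the CT line in brown. Filled points passed camera with a preset correlation of 0.01, 7 lists in the CG line and 6 in the CT line. No list passed with an estimated correlation.

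The second comparison asks the same of the C>T change in the CT line. Again only Eif3j2 passed, here in the opposite direction. It was at 58.3 ± 1.75 CPM in CT mutants and 1.47 ± 0.11 CPM in CT wild types, a log2 fold change of 5.30 ± 0.39 with an edgeR adjusted p of 0.0129. The sum of Eif3j1 and Eif3j2 differed by a log2 value of -0.06. Without CT mutant replicate 1, or without CT wild type replicate 1 or 2, Eif3j2 no longer passed, though its log2 fold change rounded to 5 in each of these fits.

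Among genes that did not pass, the higher ones with the smallest p-values were Cwc22, Fam171b, Olfr1033 and Tslp. The splicing factor gene Cwc22 had a log2 fold change of 1.95 ± 0.21 and an edgeR adjusted p of 0.124, and Fam171b 2.32 ± 0.33 and 0.279. Olfr1033 was at 0.90 ± 0.16 and the cytokine gene Tslp at 1.13 ± 0.20. The lower ones were Palld, Camp, Ptpra, Myo1d and Ltf. Palld was at -1.27 ± 0.17, Camp, which encodes a neutrophil granule antimicrobial peptide, at -1.27 ± 0.18, and the phosphatase gene Ptpra at -0.56 ± 0.09. Myo1d was at -0.53 ± 0.10 and Ltf, which encodes the neutrophil granule protein lactoferrin, at -1.56 ± 0.30. Of the cartilage genes, Col2a1 was at -0.54 ± 0.27, Acan at 0.14 ± 0.27, Sox9 at 0.10 ± 0.22 and Col10a1 at 0.25 ± 0.18. Col1a1 was at -0.23 ± 0.42 and Mki67 at -0.48 ± 0.22. None passed, with adjusted p-values from 0.958 to 0.998.

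In the CT line 6 of 29 lists passed camera with a preset correlation, all downward. With an estimated correlation none passed, each adjusted p being 0.991. Ribosomal protein genes fell by a small amount, with a median of -0.14, 3 of 80 above 0 and an adjusted p of 1.68e-13. Immediate early and dissociation stress genes fell with a median of -0.39, 1 of 17 above 0 and an adjusted p of 5.14e-06. The unfolded protein and integrated stress response list had a median of -0.21 and an adjusted p of 0.000466, led by Trib3 at -0.61 ± 0.16 and Ddit3 at -0.74 ± 0.21. Macrophage and leukocyte markers had a median of -0.96 and an adjusted p of 0.0114, led by the leukocyte gene Ptprc at -1.24 ± 0.44. Lists of MEF2 with class IIa histone deacetylases and of hypoxia and glycolysis had medians of -0.09 and -0.10 and an adjusted p of 0.0451 each. Reported miR-140-5p targets had a median of -0.04 and a camera adjusted p of 0.936. The smallest p-values among them were those of Dnpep at 0.42 ± 0.17 and Nfe2l2 at -0.30 ± 0.13. Hdac4 at -0.26 ± 0.11 and Vegfa at -0.42 ± 0.21 came next. The reported 3p targets Nrip1 and Ncoa1 were at -0.08 ± 0.12 and 0.06 ± 0.11.

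The other 23 lists had adjusted p-values from 0.0634 to 0.972 in the CT line. Without CT wild type replicate 1 the immediate early list had an adjusted p of 0.439, the stress response list 0.142 and the macrophage list 0.269, and the MEF2 and hypoxia lists had 0.708 each. Without CT wild type replicate 2 the ribosomal list had 0.068. Without CT mutant replicate 1 the macrophage list had 0.225 and the hypoxia list 0.293. The MEF2 list had 0.615 without CT mutant replicate 2 and 0.0521 without CG wild type replicate 1. Adjusted over the list alone, 1 immediate early gene was lower and no member of the other 5 lists passed. In this line both replicates 1 carried Y-linked Ddx3y at 3512 and 3669 counts, and both replicates 2 had 10 and 30. Haemoglobin genes took 0.273% and 0.166% of counts in CT wild types and 0.105% and 0.150% in CT mutants. In the CT line 734 genes had an unadjusted p under 0.05, DESeq2 called 20, and the authors' deposited table, with the same limit, lists 41.

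**Figure D3:**
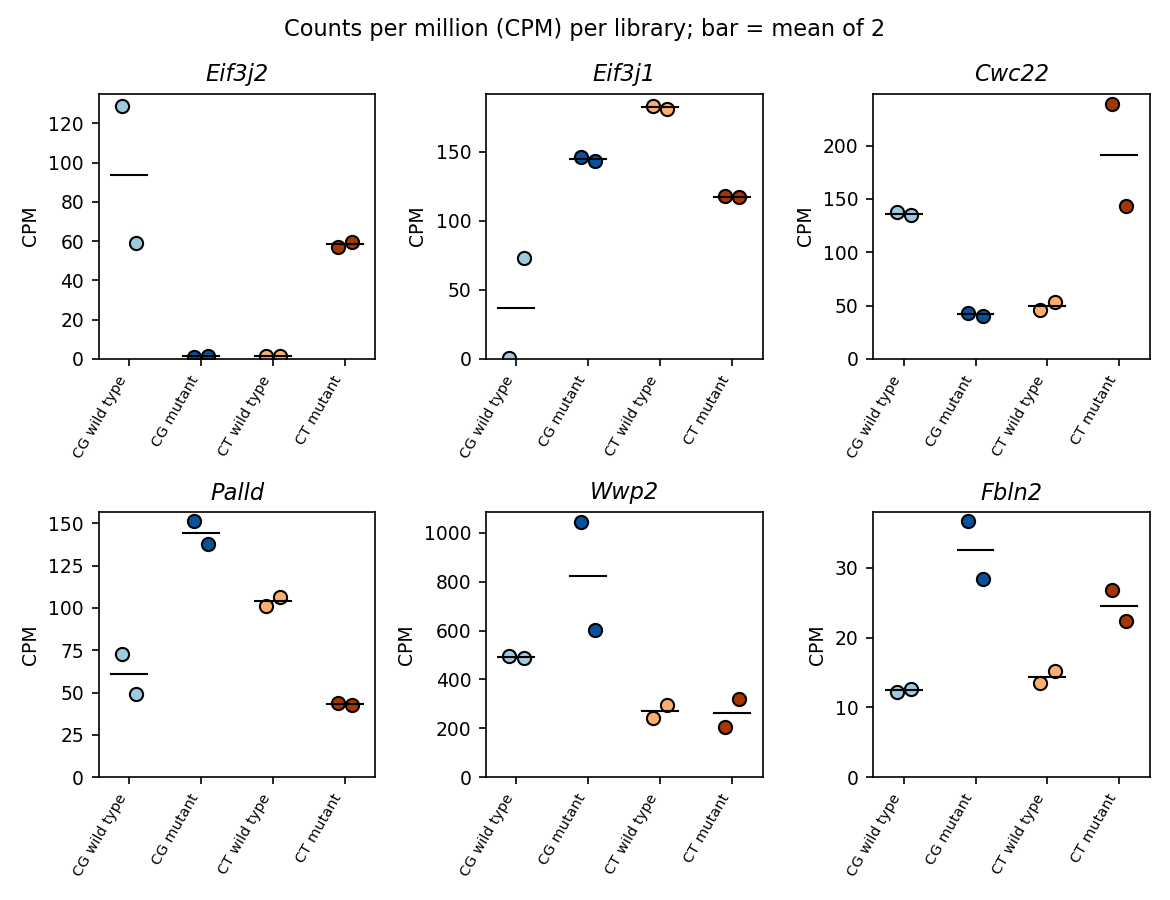
CPM of 6 genes in each library, 1 point per library with a bar at the mean of 2, by group. Eif3j2 was near 0 in CG mutants and CT wild types, and Cwc22 and Palld lay on opposite sides of their wild types in the 2 lines.

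The mean mutant effect averages the effects of both alterations, so a change in 1 line alone can carry it. No gene passed by edgeR, while 1646 had an unadjusted p under 0.05 and DESeq2 called 199. Without CG mutant replicate 2 edgeR called 319 genes. Fbln2 was highest in evidence, with a mean log2 fold change of 1.08 ± 0.11 and an edgeR adjusted p of 0.165. It was at 24.6 ± 3.09 CPM in CT mutants and 14.3 ± 1.22 CPM in CT wild types. The other higher genes were the decoy receptor gene Tnfrsf23 at 0.63 ± 0.09, Oaf at 0.40 ± 0.06, S1pr2 at 0.54 ± 0.08 and the stem cell receptor gene Lgr6 at 0.56 ± 0.09. The lower genes were Pik3cd, a leukocyte phosphoinositide 3-kinase subunit gene, at -1.22 ± 0.15, Ccl5 at -0.63 ± 0.09 and Pcdh9 at -0.78 ± 0.12. Cmc2 was at -0.53 ± 0.09 and Ephx1 at -0.64 ± 0.10. Each of these lower genes had an edgeR adjusted p of 0.243. Cmc2 was at 44.5 CPM in both CT groups, and Ccl5 at 209 ± 1.2 CPM in CT mutants and 216 ± 35.9 CPM in CT wild types. Their mean effects therefore came from the CG line. Pik3cd, Pcdh9 and Ephx1 were at 18.3, 10.3 and 32.1 CPM in CT mutants, against 33.4, 14.7 and 39.5 CPM in CT wild types. Wwp2 was at 0.35 ± 0.20, Col2a1 at -0.09 ± 0.19, Acan at 0.34 ± 0.19, Sox9 at 0.23 ± 0.15, Col10a1 at 0.06 ± 0.13, Col1a1 at -0.42 ± 0.30 and Mki67 at -0.34 ± 0.16, none passing. Of the reported targets, Nfe2l2, Hdac4, Dnpep and Adamts5 were at -0.35 ± 0.09, -0.23 ± 0.08, 0.25 ± 0.12 and -0.65 ± 0.32, and Nrip1 and Cd38 at -0.18 ± 0.09 and -0.17 ± 0.26.

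For the mean effect over both lines, 6 of 29 lists passed camera with a preset correlation, all downward. With an estimated correlation none passed, the smallest adjusted p being 0.809. Immediate early genes had a median of -0.36 with 1 of 17 above 0 and an adjusted p of 3.47e-07, and ribosomal protein genes -0.08 and 9.4e-06. Macrophage markers had a median of -0.55 and an adjusted p of 0.000714, and inflammatory genes -0.26 and 0.00659. The MEF2 list had -0.09 and 0.0308, and tendon genes -0.27 and 0.0461. In the CT line alone inflammatory genes had a median of 0.06 with 10 of 20 above 0, and tendon genes -0.02 with 3 of 6. In the CG line alone ribosomal protein genes had a median of -0.02. The mean calls of these lists therefore rested on 1 line. Immediate early, macrophage and MEF2 lists had negative medians in each line. The macrophage median was -0.20 and the inflammatory median -0.13 without CG mutant replicate 1, against -1.26 and -0.58 without CG mutant replicate 2. The other 23 lists had adjusted p-values from 0.118 to 0.926. Without CG mutant replicate 1 the inflammatory list had an adjusted p of 0.608, the tendon list 0.651 and the macrophage and MEF2 lists 0.0908 each. The ribosomal list had 0.12 without CT wild type replicate 2. The inflammatory list had 0.0751 without CG wild type replicate 2 and 0.106 without CT wild type replicate 1. The MEF2 list had 0.0727, 0.137 and 0.135 without CG wild type replicate 1, CT wild type replicate 1 and CT mutant replicate 2. The tendon list had 0.0727, 0.0751, 0.0887 and 0.113 without CG wild type replicate 1 or 2, CT wild type replicate 2 and CT mutant replicate 1. Immediate early genes passed whichever library was left out, but their median was -0.19 without CT wild type replicate 1 and -0.55 without replicate 2. Of these genes 4 were lower adjusted over the list alone.

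Across genes, the effects of the 2 mutations had a Pearson r of 0.163 and a Spearman rho of 0.239 over 14359 genes, and 58.8% of genes had the same sign. Genes are not independent replicates, and the 2 effects share no library. Without CT wild type replicate 1 the r was 0.037 and 50.5% of genes had the same sign. At an unadjusted p under 0.05, 88 genes were higher in both lines against 22.9 for independent lists, and 57 were lower in both against 18.6. In opposite directions, 14 genes were higher in CG and lower in CT mutants, and 18 the reverse, against 24.8 and 17.2.

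A test of the difference between the lines in the mutant effect called 3 genes. Eif3j2 differed by a log2 value of -11.62 ± 0.57, Cwc22 by -3.66 ± 0.30 and Palld by 2.52 ± 0.23, with edgeR adjusted p-values of 0.00053, 0.0148 and 0.0239. Cwc22 was at 41.6 ± 2.34 CPM in CG mutants and 136 ± 2.33 CPM in CG wild types, and at 191 ± 67.5 and 49.5 ± 4.88 CPM in the CT line. Palld was at 144 ± 9.62 and 60.9 ± 16.6 CPM in the CG line, and at 43 ± 0.81 and 104 ± 3.82 CPM in the CT line, mutants first. The next genes, which did not pass, were Lmcd1 at 1.44 ± 0.24, Dph6 at 1.20 ± 0.22, Creb3l1 at 0.79 ± 0.15 and Ptpra at 0.60 ± 0.12, and on the lower side Dio2 at -1.36 ± 0.17, Srp54a at -1.15 ± 0.15 and Fam171b at -3.13 ± 0.46. Palld did not pass when any CT library was left out, and Cwc22 did not pass without either CT wild type library. Without CT wild type replicate 1 only Eif3j2 passed, and without CG mutant replicate 2 there were 97 genes. DESeq2 called 38, and 687 genes had an unadjusted p under 0.05.

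Sites for the 2 arms of miR-140 in 3′ UTRs bore no shift that passed a test. In the CG line the 1552 genes with a site for the 5p arm had a median log2 fold change that differed by -0.028 from the 12329 genes without, with a camera p of 0.33, and in the CT line the difference was -0.007. For the 3p arm, with 2675 genes, the differences were 0.001 in the CG line and 0.019 in the CT line. All adjusted p-values were 0.837. With 8-base sites only, the 289 genes for the 5p arm differed by -0.054 in the CG line, with a p of 0.0249 and an adjusted p of 0.153. After regression on UTR length and GC, the 5p site AACCACT lay at percentile 62.6 of 16199 7-mers in the CG line, 1.7 in the CT line and 4.4 for the mean effect, counted from the most negative. Without the regression the percentile of the 5p site was 39.7, 8.7 and 5.4. The 3p site CTGTGGT lay at percentiles 97.8, 92.9 and 96.1, and without the regression at 97.7, 75.1 and 96.5. In the CG line its difference was 0.013 after the regression, in a range from -0.151 to 0.067, and 0.001 without it. The 5p difference of -0.008 after the regression lay at percentile 62.6, so most 7-mers lay below 0 in this line. A high percentile there can therefore go with a shift near 0. The 5p difference in the CT line was -0.031 after the regression, in a range from -0.09 to 0.073 over all 7-mers. These ranks describe these libraries, since genes are not replicates.

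Between the wild types, many haemoglobin, glycolytic and cell cycle genes were higher in the CT line than in the CG line, and most inflammatory genes and 5 of 21 matrix protease genes were lower. Of 14359 genes, 4843 differed, 2436 higher and 2407 lower in CT wild types. With limma on log2(FPKM + 1) the split was 3248 higher and 1567 lower, and with log2(FPKM + 0.1) it was 3207 and 1592, a scale on which the median of all genes moved by 0.126. Without CG wild type replicate 2 the count was 2137, without replicate 1 it was 2431, and without CT wild type replicate 2 it was 3092, each more than 1.5 times below. Line, strain history, culture and library batch cannot be told apart here.

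The largest rises were those of erythroid genes. The haemoglobin gene Hba-a1 was at 1010 ± 233 CPM in CT and 5.53 ± 0.19 CPM in CG wild types, a log2 fold change of 7.5 ± 0.52 with an edgeR adjusted p of 0.00017. The haem synthesis gene Alas2 had a log2 fold change of 7.67 ± 0.52, and the red cell anion exchanger gene Slc4a1 6.38 ± 0.69. Hbb-b1 and Hbb-b2 had 0 counts in both CG wild types and were at least 7140-fold and 1090-fold higher against a floor of 3 counts per library. The largest falls were those of Chit1, a macrophage chitinase gene, at -6.29 ± 0.67, C1rb at -6.15 ± 1.36, Eif3j2 at -5.99 ± 0.40, the macrophage elastase gene Mmp12 at -5.43 ± 0.34 and the channel gene Asic3 at -5.42 ± 0.52. C1rb did not pass without either CT wild type library.

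Of 29 lists, 11 passed camera with a preset correlation between the wild types. With an estimated correlation none passed, the smallest adjusted p being 0.374, while 10 passed fry. Hypoxia and glycolysis genes rose, 15 of 21 passing, with a median log2 fold change of 0.82 and an adjusted p of 8.45e-08, among them Pfkl at 2.41 ± 0.11 and the mitophagy gene Bnip3 at 2.78 ± 0.16. In the cell cycle list 13 of 23 were higher and 1 lower, with Mcm3 at 1.5 ± 0.12 and Top2a at 1.36 ± 0.17. Erythroid genes were higher in 7 of 9, cholesterol synthesis genes in 8 of 17 and endothelial markers in 5 of 11. Ribosomal protein genes were higher in 10 of 80. The unfolded protein and stress response list fell, 15 of 16 passing with a median of -0.89, including Trib3 at -2.21 ± 0.17 and Ddit3 at -1.83 ± 0.21. In the inflammatory and NF-kB list 15 of 20 were lower with a median of -2.07, including the acute phase genes Saa3 at -4.94 ± 0.26 and Lcn2 at -4.15 ± 0.35 and the cytokine gene Il6 at -5.03 ± 0.73. In the matrix protease list 5 of 21 were lower, including Mmp3 at -4.72 ± 0.30 and Mmp13 at -3.21 ± 0.43. Smooth muscle markers were lower in 4 of 8, with Acta2 at -1.92 ± 0.22, and skeletal muscle genes in 6 of 10 with 1 higher. Without CT wild type replicate 2 the endothelial list had an adjusted p of 0.0728 and the ribosomal list 0.0785, and without CT wild type replicate 1 the skeletal muscle list had 0.0758. Macrophage and leukocyte markers, unlike Chit1 and Mmp12, were mostly above 0, 11 of 12 with a median of 1.27, 6 passing as higher and 1 as lower. That list did not pass, with an adjusted p of 0.0724. Chondrocyte matrix genes went both ways, 10 higher, among them Comp at 2.21 ± 0.13 and Col9a1 at 2.40 ± 0.23, and 5 lower, with an adjusted p of 0.284. The 18 lists that did not pass had adjusted p-values from 0.0724 to 0.917. Adjusted over the list alone, 15 hypoxia genes and 15 cell cycle genes were higher, and 17 inflammatory genes and 1 cell cycle gene were lower.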

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

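The comparison of the summed copies, the test of blood cells in the wild types and the splits of the libraries were set before their results were seen; the tests of a shared miR-140-5p effect, of outbred alleles and of sex and the splits compared at an unadjusted p were chosen only after, and the bound for alleles was restated once the values were known. The lines differed in the mutant effect for 3 genes by the edgeR test of the difference, Eif3j2 at -11.62, Cwc22 at -3.66 and Palld at 2.52 on the log2 scale. They also differed for 5 gene lists by camera with a preset correlation, none of which passed with an estimated one (smallest adjusted p of 0.662). The median difference, CG effect minus CT effect, was 0.48 for the chondrocyte matrix list, 0.31 for the unfolded protein and stress response list, 0.11 for ribosomal protein genes, -0.19 for cell cycle genes and -0.60 for inflammatory genes. The inflammatory difference was -0.26 without CG mutant replicate 1 and -1.41 without CG mutant replicate 2. Without CG mutant replicate 1 the chondrocyte list differed by 0.03 and the cell cycle list by -0.06, and both lost their calls. The cell cycle list also lost its call without CT mutant replicate 2, at -0.14, and without CT wild type replicate 1, at -0.19. Without CT wild type replicate 2 the ribosomal list had an adjusted p of 0.396 and the inflammatory list 0.0906, and without CT wild type replicate 1 the stress response list had 0.0961.

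Eif3j2, Cwc22 and Palld moved in opposite directions in the 2 lines. A higher level of miR-140-5p in both mutants would move a gene the same way in both lines, and by itself would not give these opposite signs. These genes were picked because the difference passed, which favours opposite signs. The signs therefore cannot decide whether that level was higher or what it changed. For Eif3j2, the sum with Eif3j1 moved by at most 0.15 on the log2 scale in either line while Eif3j1 went up in CG and down in CT mutants, which is consistent with reads passing between near-identical copies. Eif3j1 was at 0.652 and 73.2 CPM in the 2 CG wild types, so the copies differ between libraries of 1 group. Alleles that vary between animals of the outbred CD1 strain may lie behind this, but the largest gap within a group was 1.13 for Eif3j2 against 0.74 for Cwc22 and 0.56 for Palld, and with no genotypes this cannot be told apart from an effect of the mutations for the last 2 genes.

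The wild types of the lines differed in 4843 genes. Blood and marrow cells in the CT cultures could bring the haemoglobin and myeloid genes. Without these and the genes that followed them within groups 84.1% of the calls were left. Genes were matched on deviations between the 2 libraries of a group, so some brought by such cells could be missed. The share left therefore cannot decide how far such cells are the cause. Each wild-type group has 1 library with and 1 without Y-linked Ddx3y, a difference of 0 libraries, so sex is balanced between them, which argues against it as the cause. The labels name no batch of culture, library or sequencing. The component that separates the lines holds 64.5% of the variance, and a batch that followed the line could not be told apart from the line itself. A biological difference between the lines stays open and untested.

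For the mean mutant effect, the real split of the 8 libraries into 4 and 4 gave 0 genes by edgeR. All 35 splits give at least that many by necessity, so this count says nothing about chance. At an unadjusted p under 0.05 the real split gave 1639 genes, and 4 of the 35 splits, the real one included, gave at least as many. The splits are not alike, as some divide the lines unequally and some keep both CG mutant libraries together. Their share therefore cannot decide about chance, which is not excluded. The highest other split, that by line, gave 7316 genes past the threshold and 8245 at an unadjusted p, which points to the structure of the samples, and the highest that did not follow the line gave 2904. Every split was fitted with a term for the line except the split by line, which was fitted without one. Its counts therefore come from another model than those of the real split and the other splits.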

How the results depend on the processing

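The robust fit, the sex term, the crossed block and the list tests between the wild types were chosen after the data were seen. Counts of genes past the edgeR threshold in CG, CT, mean and difference effects were 1, 1, 0 and 3, and by DESeq2 they were 205, 20, 199 and 38. With no filter on low counts they were 13, 2, 1 and 5. Limma on log2(FPKM + 1) gave 4 in the CG and 3 in the CT line, and log2(FPKM + 0.1) gave 3 in the CG line. A fit of the CG libraries alone gave 1 gene, Cwc22, so that Eif3j2 lost its call. A fit of the CT libraries alone gave 3, and the sex term gave 2 for CG and 1 for the mean effect. The replicate numbers are not known to pair the libraries, same-numbered deviations correlating at -0.17 in the CG and 0.38 in the CT line. The replicate block gave 4 genes for CT, 5 for the mean, 6 for the difference and 2756 for the wild types, and 8 lists for the difference. The block crossed in the CG line gave 2 genes each for CG, CT, the mean effect and the difference, where Cwc22 and Palld lost their calls. A 2-fold minimum left 1795 genes between the wild types. The r between the mutant effects was 0.037 with no filter and 0.037 to 0.194 when libraries were left out. RLE size factors, the stricter filter and the robust fit kept each gene count within 1.5 times its value. The causes of these shifts were not tested.

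Leaving out each library gave 1 to 522 genes for CG, 0 to 4 for CT, 0 to 319 for the mean effect, 1 to 97 for the difference and 2137 to 5324 for the wild types. The highest CG, mean and difference counts came without CG mutant replicate 2, which leaves the deviating replicate 1 as the lone CG mutant, assumed to vary like the other groups. Lists past the threshold numbered 4 to 13 for CG, 2 to 8 for CT, 3 to 15 for the mean and 4 to 14 for the difference. Camera with an estimated correlation called 0 lists in every comparison, and fry in its directional form called 0 for the CG, CT, mean and difference effects. Fry in its form for members moving either way called the hedgehog signalling list for the CG effect, with an adjusted p of 0.000132. It also called that list for the mean effect, with an adjusted p of 0.000348. In CG mutants 5 members of the list were above 0 and 6 below.

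No seed match set passed under any setting run, but small differences changed sign. When 1 library was left out the 3p set ranged from -0.004 to 0.008 in CG, from -0.002 to 0.038 in CT, from -0.002 to 0.019 for the mean and from -0.042 to 0.006 for the difference. The 5p set ranged from -0.041 to 0.019 in CT. In CG the 3p set was at -0.01 with the sex term and at 0.026 with 8-base sites only. Without the regression the 5p site lay at percentile 39.7 in CG and 8.7 in CT, and the 3p site at 75.1 in CT. Among named genes the direction changed only when 1 library was left out. In CG, Col2a1 ranged from -0.07 to 0.70, Sox9 from -0.05 to 0.69, Col10a1 from -0.44 to 0.12 and Mki67 from -0.45 to 0. In CT, Wwp2 ranged from -0.39 to 0.25, Sox9 from -0.03 to 0.22, Col1a1 from -0.59 to 0.06, Nrip1 from -0.25 to 0.11 and Ncoa1 from -0.03 to 0.16. For the mean effect, Col2a1 ranged from -0.31 to 0.08 and Col10a1 from -0.09 to 0.18. Of 1648 values of named genes under other settings, 1533 kept direction and side of the threshold, 88 gained and 15 lost the call.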

Other observations

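The lists of p53 targets and neutrophil genes and the tests in this part were chosen after the data were seen. Genes known as targets of the tumour suppressor p53 were lower in CG mutants. Of 32 measured members 26 had a negative log2 fold change, with a median of -0.49, and 19 were lower and 1 higher adjusted over the list alone, though none passed over all genes. The examples were Ccng1 at -0.83 ± 0.11, the cell cycle inhibitor gene Cdkn1a at -0.66 ± 0.11 and Eda2r at -1.06 ± 0.18. In the CT line 24 of 32 were negative with a median of -0.07. In the CT line neutrophil and bone marrow genes had a median of -1.44 in mutants, with 13 of 21 lower adjusted over the list alone and 0 over all genes. The list includes genes that drew attention, such as Camp and Ltf. Without the 7 members among the 45 smallest p-values the median of the other 14 was -1.26, with a camera p of 3.06e-07 with the preset and 0.113 with an estimated correlation, so a lower level of the group is not established. Of the 21 members 14 were higher and 2 lower in CT than in CG wild types, with a median of 2.61.

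A hypothesis is that p53 activity was lower in the CG mutants, which may be an effect of the mutation or of how these cells had been kept. The 6 members among the 45 smallest p-values, which drew most attention, were left out. The other 26 members had a median of -0.40, 20 of them negative, and a camera p of 0.0165 with an estimated correlation. The list was chosen after the CG values were seen, and leaving out these members does not undo that choice. This p therefore describes these libraries and is no independent test of the hypothesis. Without CG mutant replicate 1 the p was 0.0267, and without replicate 2 it was 0.0979. The median difference of the 26 members between the lines was -0.27, with a p of 0.0342 with an estimated correlation, though the list itself was picked for low values in CG mutants. The 2 libraries per group do not separate the mutation from differences between cultures.

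Cmc2, Cyb5b and Gcsh, which had small p-values in the CG line, lie within 100 tested genes of Wwp2, and a carried chromosome segment around the edited gene could be the cause. In the window of 100 tested genes on each side of Wwp2, 26 of 200 genes had an unadjusted p under 0.05, a share of 13%. Other windows of that size had a median of 10.5% and a 95th percentile of 17%, and the window lay at percentile 72.7, with 77.7 and 23.6 for windows of 25 and 50 genes per side. In the CT line the percentiles were 32.6, 6.8 and 2 for 25, 50 and 100 genes per side. A share under the 95th percentile does not exclude a segment, so this stays open.

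The authors' deposited table of comparisons lists few genes that were lower in CT wild types. Of the 2407 genes lower by edgeR it held 29, and of the 2436 higher it held 2067. Among genes that changed at least 2-fold it held 15 of 938 lower and 736 of 857 higher. Directions in that table were therefore not counted for any comparison.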
